A study of Mus musculus with 12 samples.

How the data were processed

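RNA of sorted mouse B cells was measured on 12 Affymetrix mouse arrays. Per the labels, cells of female C57BL/6 mice were sorted by flow cytometry without culture, total RNA was isolated with a picoPure kit, and biotin-labelled cRNA was made by the standard Affymetrix protocol. The labels name the cell types but not the surface markers of the sort. The values deposited by the authors are intensity on a linear scale, from 3.00 to 22068. Across the 12 arrays the median ran from 44.0 to 49.2 and the 75th percentile from 346 to 412. Per the submitters' processing notes, RMA and affy were used, and their versions are not given in the sources used here. The order of these steps, the background correction and the summarisation are not given in the sources used here either.

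The log2 of each intensity was taken before any test. Of 45037 probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. Each gene was represented by its probe set with the highest mean over the 12 arrays among those with 1 symbol, which left 18193 genes, 9010 of them with more than 1 probe set. Probe sets with several symbols or none were left out, and no filter on dim probe sets was applied. The symbols of 34741 probe sets were matched by gene identifier to the reference gene table, and 0 of them had to be updated.

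The arrays fall into 4 groups of 3. All 12 were fitted in 1 linear model with 4 group means with limma 3.58.1 (R 4.3.3; lmFit and eBayes, without trend or robust fitting), which gave 8 residual degrees of freedom and a prior of 2.37. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Differences are log2 values with the standard error of the limma fit, and the adjusted p values are those of limma. The labels do not say whether the 3 replicates are separate mice, pools or repeated sorts, so the p-values measure only the spread between these samples. The number of arrays limits the precision.

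Gene lists were written from general knowledge of B cells before the data were examined, 33 in all, with markers of 7 other cell types among them. The list of T-bet and CD11c B cell genes rests partly on work that followed this study. Each list was tested in each of 4 comparisons with camera at a preset correlation of 0.01, and the 132 p-values were adjusted together. The same tests were run with an estimated correlation, and fry was run beside them. Members called are counted over all genes and also adjusted over the list alone.

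The genes named in the text follow a rule set before the data were examined. In each comparison it takes the 8 called genes with the largest difference in either direction whose groups do not overlap and whose higher group lies at or above the median of all probe sets. It adds the members of a list with the lowest p, up to 4 a list, the called other cell type markers of at least 2-fold, and a set of B cell genes whatever their result. Predicted genes, clone names and immunoglobulin segments were passed over.

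The alternatives were other limma settings, array weights, fits of the compared groups alone, the replicate number as a block, cyclic loess, centring, a filter on dim genes, other rules for the probe set, an adjusted p under 0.01, and leaving out each array. After the data had been seen, 3 more were added for the gene counts: a fit without the 2 arrays that stand apart, a repeated quantile normalization, and the 75th percentile of each array as a covariate. For the lists 3 were added, each at either correlation: tests without those 2 arrays, without old B1 replicate 3, or without Itgax and Itgam. Counts were also recomputed for other splits of the arrays into groups of the same sizes. All 10 splits were used for 6 arrays, and 100 splits were drawn at random where there are more. Splits that only exchange 2 groups without changing the count were taken once.

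The procedure was tested on simulated data with 18193 genes, of which 200 were changed, 50 at each of 4 sizes. Of the 50 genes changed by a log2 of 1, between 33 and 40 were called in the 4 comparisons, all in the right direction. Between 9 and 11 unchanged genes were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.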

Results

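The series compares 3 kinds of sorted mouse B cells: age-associated B cells (ABC) and follicular B cells (FO) from the spleen, and B1 cells from the peritoneal cavity, which the sample titles call B1a and the cell type field B1. ABC, FO and B1 cells came from mice older than 15 months, and another group of B1 cells came from mice of 8 weeks. Each group holds 3 arrays. The median intensity per array ran from 44.0 to 49.2. Its 75th percentile was 346 in old B1 replicate 3 and 378 in old FO replicate 2, against 400.1 to 412 in the other 10 arrays. The same 2 arrays had the lowest weights that limma gave to the arrays, 0.102 and 0.349. The counts without both of them, and list tests without both or without old B1 replicate 3, were chosen after the data had been seen. Below, ± is the standard error of a log2 difference, n is 3 arrays per group and adjusted p values are those of limma, or of camera where it is named.

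**Figure D1:**
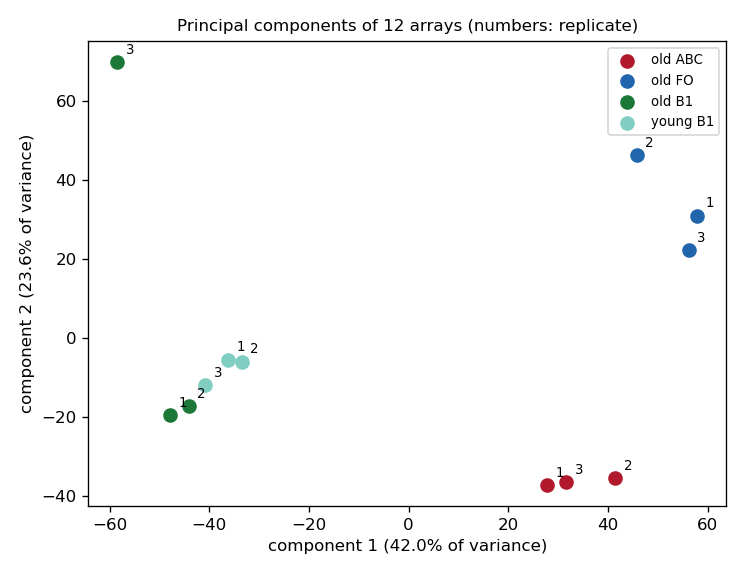
Each point is 1 of 12 arrays on the first and second principal components of log2 intensity, which hold 42.0% and 23.6% of the variance, with the replicate number beside it. Old B1 replicate 3 lies apart from the other B1 arrays along the second component.

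Old ABC against old FO cells asks what sets age-associated B cells apart from the main resting B cell of the same organ and age. ABC held more RNA of Tbx21, which encodes the transcription factor T-bet, by 3.16 ± 0.25 on the log2 scale (8.96-fold, adjusted p = 2.7e-05). They also held more Cd80, a costimulatory ligand (4.38 ± 0.26, adjusted p = 4.7e-06), more Cd86, another such ligand (1.86 ± 0.21, adjusted p = 2.6e-04), and more Cxcl10, a chemokine (4.08 ± 0.27, adjusted p = 9.2e-06). Cr2, the complement receptor CD21, fell by 2.86 ± 0.40 (adjusted p = 9.5e-04). In all, 1812 of 18193 genes were called, 1295 higher and 517 lower in ABC, and 1100 of them differed at least 2-fold (886 higher, 214 lower).

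The genes with the largest rise were Anxa8, an annexin (6.07 ± 0.34), Itgax, which encodes CD11c (5.92 ± 0.63), Apoc2, a cofactor of lipoprotein lipase (5.72 ± 0.61), and Fzd6, a Wnt receptor (5.47 ± 0.58). S1pr5, a receptor for sphingosine 1-phosphate, rose by 5.38 ± 0.40, Ramp3, a partner of calcitonin receptor-like receptor, by 5.35 ± 0.35, D7Ertd128e by 5.34 ± 0.60, and Pik3r6, a regulatory subunit of PI3 kinase, by 5.06 ± 0.47. Without old FO replicate 1, Itgax rose by 5.32 and Apoc2 by 5.11. The labels do not name the sort markers, and Itgax, which dendritic cells also express, and Itgam (CD11b, 3.41 ± 0.31) are possible ones. Other surface proteins, such as those of Cr2, Fcer2a, Cd5 and Spn, could be too, and no list test left these out. The largest falls were those of Crisp3 (-4.10 ± 0.33), Tmem108 (-3.93 ± 0.51), Gad1, which makes GABA (-3.62 ± 0.50), Ryr2, a calcium release channel (-3.48 ± 0.34), Zfp608 (-3.11 ± 0.56), Csrp2 (-3.03 ± 0.36) and Dnah8, an axonemal dynein (-2.97 ± 0.44). Fcer2a, the low-affinity IgE receptor CD23, fell by 3.23 (adjusted p = 0.0251). That call was lost when FO replicate 1 (adjusted p = 0.0737), FO replicate 2 (0.0687), FO replicate 3 (0.0777), ABC replicate 2 (0.0975) or ABC replicate 3 (0.0713) was left out.

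Of the 19 measured genes of the T-bet and CD11c list, 15 rose, 0 fell and 4 were not called (17 rose adjusted over the list alone), and the camera test gave adjusted p = 2.2e-21, or adjusted p = 0.00572 with an estimated correlation. Without Itgax and Itgam, left out after the data had been seen, 13 of 17 rose, 0 fell and 4 were not called (15 rose adjusted over the list alone), with a camera adjusted p = 1.4e-18, or adjusted p = 0.00439 with an estimated correlation. Besides those named, Itgb1, an integrin subunit, rose by 3.35 ± 0.19, Lgals1, a galectin, by 2.13 ± 0.13, and Fas, a death receptor, by 2.51 ± 0.25. Of 13 B1 cell markers, 8 rose, 1 fell and 4 were not called (10 and 1 adjusted over the list alone). Camera gave adjusted p = 5.9e-10, or adjusted p = 0.16 with an estimated correlation. Zbtb32 (4.07 ± 0.30), Sox5 (3.45 ± 0.23) and Bhlhe41 (2.96 ± 0.26), which encode transcription factors, and Spn (CD43, 3.03 ± 0.32) were among the 8, and Il5ra, the interleukin 5 receptor, was the 1 that fell (-1.74 ± 0.47). Cd5 differed by 1.12 ± 0.43 and was not called (adjusted p = 0.157). Of 11 memory B cell genes 7 rose, 0 fell and 4 were not called (7 and 1 adjusted over the list alone). The camera test gave adjusted p = 4.6e-07, or adjusted p = 0.161 with an estimated correlation. Nt5e, the ectonucleotidase CD73, rose by 4.46 ± 0.45. Of 15 plasma cell genes 8 rose, 0 fell and 7 were not called (10 rose adjusted over the list alone). By camera the list had adjusted p = 4.8e-06, or adjusted p = 0.299 with an estimated correlation. Sdc1, or CD138, rose by 1.86 ± 0.30 and Derl3, a protein of the endoplasmic reticulum, by 1.73 ± 0.30.

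Of 12 follicular markers 6 fell, 0 rose and 6 were not called (9 fell adjusted over the list alone). For the list as a whole camera gave adjusted p = 5.2e-06, or adjusted p = 0.299 with an estimated correlation. Vpreb3 (-2.22 ± 0.32) and Cd55, a regulator of complement (-1.80 ± 0.19), were among those that fell. Of 22 genes of the type I interferon response 9 fell, 1 rose and 12 were not called (11 and 2 adjusted over the list alone). As a group they had a camera adjusted p = 4.4e-05, or adjusted p = 0.332 with an estimated correlation. Usp18, a regulator of interferon signalling, fell by 1.70, Rtp4 by 1.98 and Oasl1 by 1.55. Of 18 inhibitory receptors 8 rose, 2 fell and 8 were not called (11 and 3 adjusted over the list alone). Tested together with camera they gave adjusted p = 9.4e-04, or adjusted p = 0.231 with an estimated correlation. Lag3 rose by 2.98 ± 0.46 and Cd300a by 2.22 ± 0.27. Of 23 genes of Toll-like receptor sensing 6 rose, 0 fell and 17 were not called (10 and 1 adjusted over the list alone). Camera gave adjusted p = 0.00426, or adjusted p = 0.167 with an estimated correlation. Tlr12 rose by 2.78 ± 0.19 and Tlr2 by 1.27 ± 0.15, while Tlr7 (0.94 ± 0.29, adjusted p = 0.0757) and Tlr9 (0.34 ± 0.13, adjusted p = 0.14) were not called.

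**Figure D2:**
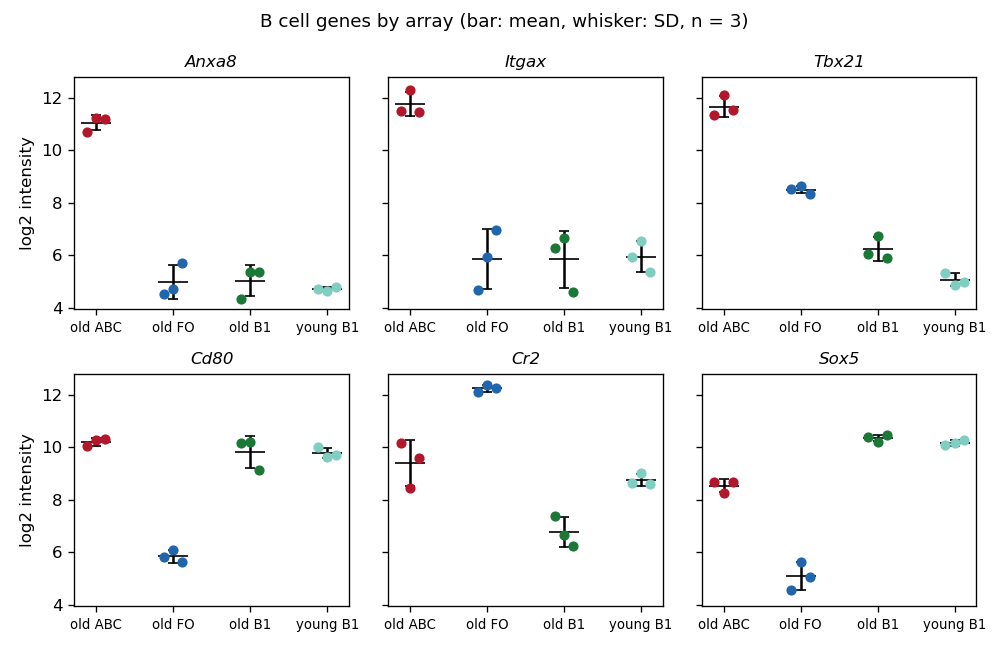
Points are the log2 intensity of 6 genes on each of 12 arrays, with the mean as a bar and the standard deviation as a whisker (n = 3). Anxa8 and Itgax lie higher in ABC than in the other groups, and Cd80 and Sox5 lie lowest in FO.

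Markers of other cell types moved with the ABC group. Of 19 macrophage and monocyte markers 12 rose, 0 fell and 7 were not called (15 adjusted over the list alone). The camera test gave adjusted p = 1.4e-09, or adjusted p = 0.332 with an estimated correlation. Adgre1, or F4/80, rose by 4.27 ± 0.40, Lyz2, a lysozyme, by 3.22 ± 0.48 and Cd163, a scavenger receptor, by 2.16 ± 0.35. Of 12 neutrophil markers 7 rose, 0 fell and 5 were not called (11 adjusted over the list alone). By camera the list had adjusted p = 2.0e-08, or adjusted p = 0.235 with an estimated correlation. Ltf, or lactoferrin, rose by 4.18 ± 0.63 and Camp, an antimicrobial peptide, by 4.69 ± 0.85. Without FO replicate 1 Ltf rose by 3.49 and Camp by 3.60, and without FO replicate 3 Camp rose by 5.74. Of 14 dendritic cell markers 5 rose, 0 fell and 9 were not called (6 rose adjusted over the list alone). The dendritic list had a camera adjusted p = 6.4e-04, or adjusted p = 0.443 with an estimated correlation. Sirpa, a signal regulatory protein, rose by 3.29 ± 0.35 and Itgae, an integrin subunit, by 2.94 ± 0.42. Of 9 mast cell markers 2 rose, 0 fell and 7 were not called (5 rose adjusted over the list alone). The mast cell list had a camera adjusted p = 0.0127, or adjusted p = 0.597 with an estimated correlation. Of 8 NK cell markers 2 rose, 0 fell and 6 were not called (2 adjusted over the list alone). The NK cell list had a camera adjusted p = 0.0216, or adjusted p = 0.574 with an estimated correlation. Gzma, a granzyme, rose by 4.22 ± 0.84. Of 9 erythroid and platelet markers 1 rose (camera adjusted p = 0.225). Of 12 T cell markers 1 rose (camera adjusted p = 0.127, or adjusted p = 0.774 with an estimated correlation). Camera called the T cell list higher without old B1 replicate 3 (adjusted p = 0.0439) and without the 2 arrays that stand apart (adjusted p = 0.00131), though not with an estimated correlation (adjusted p = 0.71 and 0.467). It also called, without the 2 arrays, the germinal centre (adjusted p = 0.0413), proliferation (adjusted p = 4.6e-05) and immunoglobulin constant lists (adjusted p = 0.00405) higher, with adjusted p = 0.413, 0.41 and 0.274 at an estimated correlation. Of 15 B cell identity genes 1 fell, 0 rose and 14 were not called (2 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.314). The 1 was Ebf1, a B cell transcription factor (-0.53 ± 0.13, adjusted p = 0.0294), and its call was lost without ABC replicate 1 (adjusted p = 0.119), ABC replicate 3 (0.0789), FO replicate 2 (0.0952) or FO replicate 3 (0.118). Without the 2 arrays that stand apart, 2964 genes were called (1865 higher, 1099 lower) and 1393 of them differed at least 2-fold. With the 75th percentile of each array as a covariate 2748 were called, 1682 higher and 1066 lower, and with array weights 3961. In place of 517, the count of lower genes was 321 without FO replicate 1, 308 without FO replicate 3, 320 without ABC replicate 2 and 327 without ABC replicate 3.

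**Figure D3:**
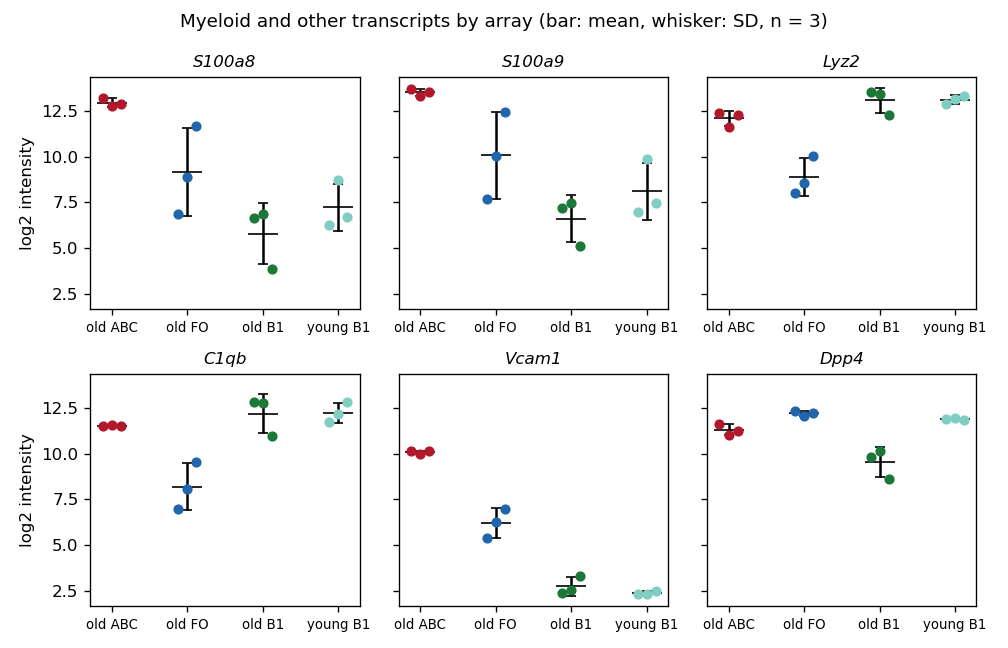
Points are the log2 intensity of 6 genes on each of 12 arrays, with the mean as a bar and the standard deviation as a whisker (n = 3). S100a8, a neutrophil transcript, runs from 6.88 to 11.7 among the 3 FO arrays and from 12.8 to 13.2 among the 3 ABC arrays.

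Old ABC against old B1 cells asks how ABC differ from peritoneal B1 cells of the same age, and the organ differs along with the cell type. ABC held more Tbx21 (5.44 ± 0.25, adjusted p = 9.5e-07), more Fas (4.66 ± 0.25, adjusted p = 1.9e-06) and more Cxcl10 (5.61 ± 0.27, adjusted p = 9.5e-07). They held less Saa3, an acute-phase protein (-7.45 ± 0.37, adjusted p = 1.1e-06), less Cxcl13, a B cell chemokine (-5.55 ± 0.45, adjusted p = 2.8e-05), and less Il6st, the gp130 subunit of the interleukin 6 receptor (-4.14 ± 0.22, adjusted p = 1.8e-06). Of 18193 genes 2334 were called, 1347 higher and 987 lower, and 1260 differed at least 2-fold (725 higher, 535 lower). A fit of these 2 groups alone called 1062 (800 at least 2-fold), and array weights gave 3592 (1425 at least 2-fold).

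Other large rises were those of Vcam1, an adhesion molecule (7.33 ± 0.35), S100a9, a calcium-binding protein of neutrophils (6.91 ± 1.12), Lcn2 (6.94 ± 0.89), Camp (6.79 ± 0.85), Ngp (6.17 ± 0.74), Anxa8 (6.03 ± 0.34) and Itgax (5.91 ± 0.63). Other large falls were those of Zfp811 (-6.95 ± 0.51), Ednrb, an endothelin receptor (-6.56 ± 0.52), Krt18, a keratin (-5.92 ± 0.48), Prg4, or lubricin (-5.44 ± 0.73), Mcpt4, a mast cell protease (-5.24 ± 0.68), and Gnb3, a G protein subunit (-5.24 ± 0.60). Without old B1 replicate 3 the differences were 6.18 for S100a9, 5.30 for Itgax, -7.29 for Ednrb, -6.34 for Prg4 and -4.62 for Gnb3. Without ABC replicate 1 they were -7.59 for Zfp811, -6.60 for Krt18 and -5.92 for Gnb3. The sizes for Vcam1, Lcn2 and Ednrb are not exact, since all arrays of the lower group lie under their own 25th percentile of intensity there (Vcam1 5.14 to 10.1 on the B1 arrays).

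Of 19 genes of the T-bet and CD11c list 11 were higher in ABC, 1 was lower and 7 were not called (12 and 2 adjusted over the list alone). For the list as a whole camera gave adjusted p = 4.6e-07, or adjusted p = 0.144 with an estimated correlation. Without Itgax and Itgam 10 of 17 were higher and 1 lower, with a camera adjusted p = 4.9e-06, or adjusted p = 0.131 with an estimated correlation. Tbx21 and Fas are among the 10. Of 17 genes of antigen presentation and costimulation 7 were higher, 0 lower and 10 not called (9 adjusted over the list alone). As a group they had a camera adjusted p = 1.2e-05, or adjusted p = 0.227 with an estimated correlation. Ciita, which switches on class II genes, was higher by 2.24 ± 0.24 and Cd40 by 1.20 ± 0.14. Of 24 cytokines and chemokines 9 were higher, 2 lower and 13 not called (13 and 2 adjusted over the list alone). Tested together with camera they gave adjusted p = 0.00152, or adjusted p = 0.235 with an estimated correlation. Lta, or lymphotoxin alpha, was higher by 3.43 ± 0.21. Of 13 B1 cell markers 5 were lower, 2 higher and 6 not called (6 and 2 adjusted over the list alone). Camera gave adjusted p = 0.00544, or adjusted p = 0.382 with an estimated correlation. Sox5 (-1.82 ± 0.23) and Ctla4, an inhibitory receptor (-3.36 ± 0.45), were among those lower. Of 12 follicular markers 5 were higher, 2 lower and 5 not called (8 and 2 adjusted over the list alone). The camera test gave adjusted p = 0.0216, or adjusted p = 0.574 with an estimated correlation. Vpreb3 was higher by 3.16 ± 0.32 and Cr2 by 2.63 ± 0.40. Tlr12 was higher by 4.02 ± 0.19, while Tlr7 (0.55 ± 0.29, adjusted p = 0.275), Tlr9 (0.34 ± 0.13, adjusted p = 0.112) and Fcer2a (1.88 ± 0.78, adjusted p = 0.161) were not called. The log2 intensity of Fcer2a was 4.74 on old B1 replicate 3, against 8.02 and 8.51 on old B1 replicates 1 and 2.

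Markers of other cell types moved with these groups too. Of 12 neutrophil markers 10 were higher in ABC, 0 lower and 2 not called (11 adjusted over the list alone). By camera the list had adjusted p = 1.7e-08, or adjusted p = 0.235 with an estimated correlation. Of 9 mast cell markers 4 were lower, 0 higher and 5 not called (4 adjusted over the list alone). For the list as a whole camera gave adjusted p = 0.0232, or adjusted p = 0.634 with an estimated correlation. Cma1, a chymase, stood at -5.18 ± 0.65. Of 19 macrophage markers 4 were lower, 1 higher and 14 not called (5 and 1 adjusted over the list alone). As a group they had a camera adjusted p = 0.00647, or adjusted p = 0.642 with an estimated correlation. Adgre1 was higher by 2.16 ± 0.40. Prg4, named above, is a member of the macrophage list. How far RNA of other cell types gives the large differences from B1 samples was not tested. Without the 2 arrays that stand apart 3189 genes were called, and 1431 differed at least 2-fold, 678 higher and 753 lower.

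The genes that set ABC apart from both other populations of old mice were those called and at least 2-fold in the same direction in both comparisons. They number 406, of which 360 were higher in ABC and 46 lower. Anxa8 led the higher ones, with Klk1b27, a kallikrein (4.91 ± 0.23 against FO, 5.22 ± 0.23 against B1), and Dnm3, a dynamin (4.73 ± 0.18 and 4.73 ± 0.18). Itgax, a possible sort marker, is counted among the 360. So are 13 markers of other cell types, 7 of them neutrophil markers, Camp, Lcn2, Ltf and Ngp among them. Lower ones include Itih5 (-2.53 ± 0.31 and -2.69 ± 0.31), Lifr, the receptor of leukaemia inhibitory factor (-2.33 ± 0.44 and -2.54 ± 0.44), and Abca1, a cholesterol transporter (-2.04 ± 0.31 and -2.08 ± 0.31). Independent lists of the same sizes would share 35.3 higher and 6.29 lower genes. Both comparisons use the same ABC arrays, and in simulated unchanged groups that share them the top lists of the same sizes shared 217.5 higher and 71.9 lower genes, while 0.02 genes on average were called in both. With 3 ABC arrays they could not be split, so part of the excess may come from the shared arrays. For the lower genes 46 lies under the simulated 71.9. The simulated top lists were ranked by p alone, without the limits of the rule, so they do not give the overlap expected under it. Without the 2 arrays that stand apart 452 genes met the rule, 370 higher and 82 lower. The lower genes numbered 71 without ABC replicate 1, 27 without ABC replicate 2 and 74 without old B1 replicate 3.

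Old B1 against old FO cells gives the distance between the reference populations, again with the organ differing along with the cell type. The B1 samples held more Tppp, a tubulin-binding protein (7.32 ± 0.20, adjusted p = 4.0e-08), and more Saa3 (8.10 ± 0.37, adjusted p = 5.5e-07). They also held more Cxcl13 (6.89 ± 0.45, adjusted p = 3.7e-06) and more Sox5 (5.26 ± 0.23, adjusted p = 5.1e-07). They held less Pcp4, a calmodulin-binding protein (-5.10 ± 0.21, adjusted p = 3.9e-07), less Vpreb3 (-5.38 ± 0.32, adjusted p = 2.0e-06), less Cr2 (-5.49 ± 0.40, adjusted p = 7.3e-06) and less Ccr6, a chemokine receptor (-5.03 ± 0.36, adjusted p = 7.6e-06). Of 18193 genes 2988 were called, 1529 higher and 1459 lower, while cyclic loess gave 1959 higher and 1114 lower. A fit of these 2 groups alone called 1455, and array weights gave 5001. The lower genes numbered 897 without FO replicate 1 and 930 without FO replicate 3.

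Other large rises were those of Zfp811 (8.37 ± 0.51), Krt18 (8.06 ± 0.48), Ahnak2 (7.70 ± 0.57) and Gng13, a G protein subunit (7.03 ± 0.54), and other large falls were those of Myl4, a myosin light chain (-4.92 ± 0.37), and Emid1 (-4.92 ± 0.31). Tmem108 was lower by 6.08 ± 0.51 and Fcer2a by 5.12 ± 0.78. Without old B1 replicate 3 the values were -5.41 for Tmem108 and -3.94 for Fcer2a, and without old B1 replicate 2 Fcer2a stood at -5.83. Of 13 B1 cell markers 12 were higher in B1, 1 was lower and 0 were not called (12 and 1 adjusted over the list alone). Tested together with camera they gave adjusted p = 2.4e-11, or adjusted p = 0.144 with an estimated correlation. Ptpn22, a phosphatase, was higher by 2.07 ± 0.16. Cd5 was higher by 1.81 ± 0.43 (adjusted p = 0.0149), or 2.45 without old B1 replicate 3, and its call was lost without B1 replicate 1 (adjusted p = 0.0531), FO replicate 1 (0.0627) or FO replicate 3 (0.0514). Of 12 follicular markers 9 were lower, 0 higher and 3 not called (9 adjusted over the list alone). Camera gave adjusted p = 2.7e-06, or adjusted p = 0.299 with an estimated correlation. Of 19 genes of the T-bet and CD11c list 10 were higher in B1, 3 lower and 6 not called (11 and 5 adjusted over the list alone). The list had a camera adjusted p = 0.00187, or adjusted p = 0.231 with an estimated correlation. Cd80 was higher by 3.99 ± 0.26, Itgb1 by 3.19 ± 0.19 and Lgals1 by 2.06 ± 0.13. Tbx21 was lower by 2.27 ± 0.25 and Fas was lower by 2.14 ± 0.25, and Itgax did not differ past the test (0.00 ± 0.63, adjusted p = 0.999).

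Of 19 macrophage markers 18 were higher in the B1 samples, 0 lower and 1 not called (18 adjusted over the list alone). The camera test gave adjusted p = 2.8e-13, or adjusted p = 0.266 with an estimated correlation. Lyz2 was higher by 4.20 ± 0.48 and Alox15, a lipoxygenase, by 7.04 ± 0.57, or 7.82 without old B1 replicate 3. How far RNA of other cell types in the B1 samples gives the large rises named above was not tested. Of 9 mast cell markers 5 were higher, 0 lower and 4 not called (6 adjusted over the list alone). By camera the list had adjusted p = 2.6e-05, or adjusted p = 0.382 with an estimated correlation. Cpa3, a carboxypeptidase, was higher by 5.54 ± 0.74. Without the 2 arrays that stand apart 4008 genes were called.

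Old against young B1 cells compares the same cell type and organ at 2 ages. Old B1 cells held more Slc41a2, a magnesium transporter, by 2.64 ± 0.13 (6.22-fold, adjusted p = 2.8e-05), more Osbpl6, an oxysterol-binding protein (3.38 ± 0.38, adjusted p = 0.00661), more Ccdc110 (1.94 ± 0.18, adjusted p = 0.00429) and more Lair1, an inhibitory collagen receptor (1.68 ± 0.18, adjusted p = 0.00596). They held less Edaradd, an adaptor of the ectodysplasin receptor (-2.14 ± 0.24, adjusted p = 0.00661), and less Rasgef1a, an exchange factor of Ras proteins (-2.10 ± 0.24, adjusted p = 0.00686). Of 18193 genes 53 were called, 29 higher and 24 lower, and 47 differed at least 2-fold (28 higher, 19 lower). The count depends on single arrays: it was 165 without old B1 replicate 3 and 17, 20 and 20 without young B1 replicates 1, 2 and 3, and the 2-fold count was 122, 17, 20 and 18. A fit of these 2 groups alone called 2 genes, 1 of them among the 53, and the replicate number as a block left 32 (30 at least 2-fold), while array weights gave 316 (178 at least 2-fold). Without the 2 arrays that stand apart 208 genes were called, 143 higher and 65 lower, and 146 differed at least 2-fold.

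Other named genes lost their call when single arrays were left out. Cubn rose by 2.81 ± 0.37 (adjusted p = 0.0116), with adjusted p = 0.0523, 0.065 and 0.0708 without young B1 replicates 1, 2 and 3. Asph rose by 1.97 ± 0.28 (adjusted p = 0.02), with adjusted p = 0.0775, 0.102 and 0.113 without young B1 replicates 1, 2 and 3. F11r, a junctional adhesion molecule, rose by 2.16 ± 0.34 (adjusted p = 0.0341), with adjusted p = 0.0704, 0.174 and 0.166 without young B1 replicates 1, 2 and 3 and 0.0661 without old B1 replicate 1. Dpp4, the peptidase CD26, fell by 2.37 ± 0.33 (adjusted p = 0.0166), with adjusted p = 0.0775, 0.0744 and 0.0861 without young B1 replicates 1, 2 and 3. Kmo, an enzyme of tryptophan breakdown, fell by 1.72 ± 0.21 (adjusted p = 0.0103), with adjusted p = 0.0554 and 0.0593 without young B1 replicates 2 and 3. Dnah8 fell by 3.12 ± 0.44 (adjusted p = 0.02), with adjusted p = 0.102, 0.0629 and 0.123 without young B1 replicates 1, 2 and 3. Ccr7, a chemokine receptor, fell by 1.20 ± 0.19 (adjusted p = 0.0307), with adjusted p = 0.0863, 0.144 and 0.123 without young B1 replicates 1, 2 and 3 and 0.0737 without old B1 replicate 1. Lta fell by 1.42 ± 0.21 (adjusted p = 0.0238), with adjusted p = 0.118, 0.0738 and 0.148 without young B1 replicates 1, 2 and 3. Dst fell by 2.23 ± 0.38 (adjusted p = 0.0449), with adjusted p = 0.227, 0.189 and 0.173 without young B1 replicates 1, 2 and 3 and 0.0517 without old B1 replicate 1.

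Of 12 follicular markers 1 fell in old B1 cells, 0 rose and 11 were not called (2 fell adjusted over the list alone). For the list as a whole camera gave adjusted p = 2.8e-04, or adjusted p = 0.382 with an estimated correlation. On old B1 replicate 3, 11 of the 12 lie below both other old B1 arrays (median deviation -0.82), and without that array camera gave adjusted p = 0.0208, or adjusted p = 0.323 with an estimated correlation. Cr2 differed by -1.99 ± 0.40 (adjusted p = 0.0987) and was not called. Of 18 inhibitory receptors 1 rose, 0 fell and 17 were not called (1 adjusted over the list alone). As a group they had a camera adjusted p = 0.0138, or adjusted p = 0.326 with an estimated correlation. Of 19 genes of the T-bet and CD11c list 0 were called by limma, with 3 at an unadjusted p under 0.05 (1 rose adjusted over the list alone). Tested together with camera they gave adjusted p = 0.0281, or adjusted p = 0.332 with an estimated correlation. Tbx21 stood at 1.16 ± 0.25 (adjusted p = 0.135). Of 9 mast cell markers 0 were called by limma, with 2 at an unadjusted p under 0.05 (1 fell adjusted over the list alone). Camera gave adjusted p = 0.00474, or adjusted p = 0.553 with an estimated correlation. All 9 lie below both other old B1 arrays on replicate 3 (median deviation -1.25), and that call was lost without it (camera adjusted p = 0.111). Without that array camera called the macrophage (adjusted p = 1.1e-07), T cell (adjusted p = 1.4e-08), NK cell (adjusted p = 3.9e-04) and dendritic cell lists (adjusted p = 0.0303) higher in old B1 samples and the proliferation list lower (adjusted p = 5.6e-05). With an estimated correlation 0 of these 5 were called without that array (adjusted p = 0.314, 0.314, 0.314, 0.458 and 0.538). Over the 4 comparisons 1377 to 5199 genes had an unadjusted p under 0.05, with 1377 in this one.

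Across the 33 lists and 4 comparisons, 47 of 132 list tests passed with the preset correlation and 1 with an estimated one, that of the T-bet and CD11c list in ABC against FO. When the 12 arrays were regrouped at random, 8 of 100 groupings, the real one included, gave at least 47 such calls and the highest other gave 60. Random groupings can thus give as many list calls, so the number of calls is no evidence by itself. Such groupings mix the cell types, whose differences then enter the spread within groups. The share of 8 of 100 is therefore not the chance level for the real groups. The list p-values with the preset correlation are to be read beside the counts of members.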

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

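The fit without the 2 arrays that stand apart, the repeated quantile normalization, the 75th percentile as a covariate, the list tests without old B1 replicate 3 or without both arrays and the lists without Itgax and Itgam were chosen after the data had been seen. Of 374 results for named genes, 354 of them called, 0 reversed with a call in those of 27 alternatives that cover them (28 to 266 results for each array left out). A reversal was counted only where the result was called in the main fit or in the alternative. Changes of sign among results called in neither are not counted. The rule named these genes largely for calls in these same arrays, so 0 reversals is weak evidence of stability. Of the 374 results, calls were lost for 88 in the fit of 2 groups, 79 at an adjusted p under 0.01, 26 with the block and 10 to 32 of 224 to 266 without an array of old mice, and for 12, 13 and 13 of 28 without a young B1 array. With array weights the genes called were 3961 for ABC against FO, 3592 for ABC against B1, 316 for old against young B1 (178 at least 2-fold) and 5001 for B1 against FO. An adjusted p under 0.01 gave 990, 1281, 15 (14 at least 2-fold) and 1706, since a stricter limit calls fewer genes. A fit of the 2 compared groups alone, with fewer arrays behind the spread, gave 1962 for ABC against FO (1198 at least 2-fold), 1062 for ABC against B1 (800 at least 2-fold), 2 for old against young B1 (2 at least 2-fold) and 1455 for B1 against FO. Without the 2 arrays 2964 genes were called for ABC against FO and 208 for old against young B1 (146 at least 2-fold). With the 75th percentile as a covariate the counts were 2748 and 80. The cause of these shifts was not tested.

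Leaving out 1 array gave 1267 to 1544 genes for ABC against FO (869 to 1001 at least 2-fold), 1609 to 2738 for ABC against B1 (1032 to 1387 at least 2-fold), 2098 to 3555 for B1 against FO, 341 to 449 for ABC apart from both, and 17 to 165 for old against young B1 (17 to 122 at least 2-fold). With the replicate number as a block the counts were 1543 (1017 at least 2-fold), 2034 (1179), 2570, 377 and 32 (30 at least 2-fold), with 47 list calls. Of 18 pairs of groups and numbers, 3 had a correlation across genes of residuals over 0.1, in a range from -0.391 to 0.228. That shows no steady pairing by number. Residuals of so few arrays a group cannot settle it, and the labels do not say what a number shares, so pairing stays unknown.

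With an estimated correlation 1 list call was left, and 1 also without Itgax and Itgam, without the 2 arrays that stand apart or without old B1 replicate 3 (47 with the preset correlation and all arrays). With the preset correlation 16 list calls were gained in the direction of the main test and 5 lost without the 2 arrays, and 10 gained and 4 lost without old B1 replicate 3. Of the list tests called with all arrays or without the 2 arrays, 4 reversed in direction without them. Lists called in neither setting are not counted, and some of those changed direction too. Without the 2 arrays the camera adjusted p values were 4.0e-04 for gene list: proliferation, old ABC minus old B1, 5.2e-08 for gene list: proliferation, old B1 minus young B1, 0.0179 for gene list: dendritic cell markers, old B1 minus young B1, and 0.0343 for gene list: T cell markers, old B1 minus old FO. Without old B1 replicate 3 the first 3 of these reversed too and were called (0.00751, 5.6e-05 and 0.0303). The T cell list changed direction there as well but was not called (camera adjusted p = 0.276). The cause was not tested beyond the deviation of that array given under the other observations. Of the 374 results 13 have a lower group under the 25th percentile of each of its arrays, where the size of a difference is not exact. Signal over background limits what dim genes can show, and the arrays give no count from which to compute that limit.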

Other observations

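Some gene groups showed few calls in ABC against FO. Of 25 proliferation genes, 14 BCL2 family genes and 21 genes of oxidative phosphorylation 0 were called by limma, where 1812 of all genes (9.96%) were called. At an unadjusted p under 0.05 these lists had 2, 4 and 1 genes, against 3718 of all 18193. The share of BCL2 family genes, 4 of 14, lies above that of all genes. The proliferation genes lay higher on old FO replicate 2, and without the 2 arrays that stand apart camera called that list higher in ABC (adjusted p = 4.6e-05, against 0.346 with all arrays), though not with an estimated correlation (adjusted p = 0.41). Of 10 senescence-associated genes 2 rose, 0 fell and 8 were not called (3 adjusted over the list alone; camera adjusted p = 0.00205, adjusted p = 0.161 with an estimated correlation). Cdkn2b, a cell cycle inhibitor, rose by 2.94 ± 0.36 (adjusted p = 3.9e-04). Of 18 genes of the unfolded protein response 4 rose, 0 fell and 14 were not called (7 adjusted over the list alone; camera adjusted p = 0.00212, adjusted p = 0.299 with an estimated correlation). Atf6, a sensor of unfolded proteins, rose by 0.98 ± 0.14. Lef1, a transcription factor of the circulation and quiescence list, fell by 1.68.

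The tests of other splits were set before their results were seen, except that mirror splits were taken once for ABC apart from both only after a first count, and all other tests of this part were chosen only after the values they rest on had been seen. For 6 arrays the 10 splits are too few for a share under 0.05, and only the real one of each gave as many genes (1 of 10 each). The real counts and the highest other were 1812 and 0 for ABC against FO (1100 and 0 at least 2-fold), 2334 and 1 for ABC against B1 (1260 and 1), 53 and 4 for old against young B1 (47 and 4), and 2988 and 0 for B1 against FO. For ABC apart from both, 3 of 100 splits, the real one included, gave at least 406 genes. That share, under 0.05, speaks only against arrays without any group difference. It cannot show that ABC in particular stand apart. Both other splits took the 3 B1 arrays as the group set apart (661 genes with ABC and FO whole, 527 with these mixed), so that split count shows the distance of B1 as well. For the list shifts 8 of 100 splits gave at least 47 calls and the highest other 60, so chance cannot be excluded for that number. Those splits mix the cell types within groups, so they cannot show that the real list shifts are at chance level either.

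Old B1 replicate 3 stood apart from the other old B1 arrays. Among genes under the median level its deviation from its group correlated across genes with that of old FO replicate 2 at 0.481. Pairs of either array with an ABC or young B1 array, and of an ABC with a young B1 array, reached at most 0.119. The remaining pairs were not compared for these genes. A technical shift shared by the 2 arrays could give the correlation of 0.481. Old B1 replicate 3 also held less of 55 of the 58 other cell type markers seen in replicates 1 and 2 (94.8%), which could come from fewer such cells in that sort. The 25 proliferation genes were all higher on it, by a median of 1.92, while the B cell identity genes had a median deviation of -0.00503, and random lists of the same brightness lay below the proliferation list in 100% of 10000 draws, so neither fewer other cells nor a shift by brightness alone accounts for that part. The same genes also lay higher on old FO replicate 2 (median 0.997, 22 of 25 above both other FO arrays), but there the germinal centre (1.22, 9 of 10), plasma cell (0.519, 15 of 15), immunoglobulin constant (1.19, 5 of 5) and T cell lists (0.831, 11 of 12) rose too, while on old B1 replicate 3 the germinal centre and T cell medians were -0.362 and -2.18. Whether the rise on the 2 arrays has a shared technical source or other cells in the sort of old FO replicate 2 stays open and was not tested, and no biological explanation was tested, since the labels give none for a single array.

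Neutrophil transcripts were higher in ABC than in FO samples, and neutrophil RNA in the sorted ABC samples is a candidate source. All 12 measured neutrophil markers had a positive difference, as neutrophil RNA would give, 6 of them lie at or above the median of all probe sets in FO samples too, and 1 belongs to another list. Of these S100a8 and S100a9 ran from 6987 to 9609 and from 10396 to 13337 on the ABC arrays and from 118 to 3234 and from 209 to 5564 on the FO arrays. The labels do not describe the markers of the sort, so how far it removed neutrophils is not known. Macrophage RNA as a source of the T-bet and CD11c list cannot be told apart from expression by ABC for the list as a set: a source that held the median member at the highest intensity on the arrays would lower the B cell identity genes by a log2 of at least 0.148, and their median was -0.0773 with a bootstrap standard error of 0.0652. The least share so computed is 9.73% for the median member but 54.9% for Lgals1, 24.8% for Fcer1g and 21.9% for Ahnak (genes picked for the highest shares, which do not decide for the list). Expression by ABC themselves and RNA of dendritic cells, NK cells or other cell types whose markers rose stay open and were not tested.

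Of the genes called in old against young B1 cells 24 were lower in old, and follicular RNA in the young samples cannot be told apart from a change in the B1 cells as their source, since no FO cells of young mice were measured. The old FO arrays were used in their place. There, 16 of the 24 would need a larger share of follicular RNA than any of 5 follicular markers allows (at most 40.5%). For 9 of these 16, old FO cells do not hold more of the gene. The limit of 40.5% was set by Ccr7, which is also among the 24 genes. By the 4 markers that were not called the limit was 8.69%, and all 24 genes would need more. These shares hold for RNA like that of the old FO arrays, and they exclude nothing for FO cells of young mice. Old B1 replicate 3 alone is not the source, since 165 genes were called without it and all 53 were among them. Age stays open as an explanation, which these arrays could not separate from other differences between the 2 sets of mice.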
